A study of Aethionema arabicum with 12 samples.

How the data were processed

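The samples were imbibed, intact, ungerminated seeds of the Cyprus accession of *Aethionema arabicum* in 4 conditions of 3 libraries each. Per the labels' protocols, polyadenylated RNA was selected and libraries were made with a SENSE mRNA-seq kit, and per the series' text they were sequenced on an Illumina HiSeq 2500 in triplicate. The labels do not say whether the 3 libraries of a condition came from separate seed batches, so p-values measure the spread between these libraries, which may be partly technical. Per the submitters' processing notes, bcl2fastq 2.17.1, Trimmomatic, Bowtie2 2.3.5.1 and HTSeq 0.11.2 were used and the build TAIR10 is named, while the gene identifiers of the table are those of *Aethionema* gene models. The role of each tool and build, duplicate handling and strand setting are not given in the sources used here.

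The table the authors deposited holds, for 24932 gene models, raw read counts per library, RPKM values, a gene length, and for 21661 models a paired Arabidopsis gene; 3271 have none. Counts were used as deposited. The deposited RPKM values equal count divided by gene length and library total (largest relative difference 3.45e-08) and were not used in any test. Of the gene lengths, 46.6% are multiples of 3, so they are called gene length and not coding length. Among the 23909 models of 300 bp or longer, 0 of 286908 values exceed 1 read per base of gene length and the highest is 0.996; 10 values do so among all models. A limit of this kind would compress the counts of highly expressed, short genes, more so in deeper libraries. The step that set this limit is not given in the sources used here.

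Conditions were taken from the sample labels, and every column of per-sample values was matched to its sample by title. Total counts per library were 916523 to 3996148, and genes left untested held 0.379% of all counts. Counts were fitted with edgeR 4.0.16 in R 4.3.3 (files read with version 1.17.8 of data.table), in 1 model with 4 group means for all 12 libraries, TMM scaling, the default expression filter (15301 genes) and the quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The common dispersion was 0.0177. All adjusted p-values printed for genes come from that test, and those of lists from the set tests below. CPM values use TMM-scaled library sizes and are means with SD over 3 libraries; log2 fold changes are edgeR's, with a standard error equal to the absolute log2 fold change over the square root of F. A gene with 0 counts in a group is given as a bound against 3 counts over the group, and one with 1 to 3 counts as a ratio with an exact 95% interval. Such intervals and bounds cover counting error only. The first 3 comparisons were 7 d against 1 d of light, 14 d against 7 d of light, and 7 d light then 7 d dark against 14 d light; 3 further comparisons used the same fit.

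Before the data were examined, 26 gene lists were fixed from Arabidopsis knowledge: ABA biosynthesis, ABA catabolism, ABA receptors and kinases, clade A PP2C phosphatases, ABA-responsive transcription factors, GA biosynthesis, GA deactivation, GA perception, dormancy regulators, seed storage and oil body proteins, LEA and desiccation, embryo maturation, nuclear photosynthesis, photoprotection, photoreceptors and light signalling, circadian clock, wall loosening, cell cycle, cytosolic ribosomal proteins, heat shock, antioxidant enzymes, dark and starvation, nitrate and ethylene, and markers of endosperm, seed coat and root. Of their 296 genes, 244 were paired with at least 1 gene model, 300 models in all. Lists with 5 or more tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it, adjusted over lists within a comparison. Camera compares a list with all other genes; fry asks whether the genes of a list move, on balance, in a single direction.

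The rule for naming genes was also fixed before the data were examined. It took, per comparison, the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 8 CPM over the 12 libraries, no overlap between the groups and a paired Arabidopsis symbol or description, up to 4 called members of each list with the smallest adjusted p, and allowed any tested member of the ABA biosynthesis, ABA catabolism, GA biosynthesis, GA deactivation and dormancy lists. Further comparisons name genes already named, and tissue checks may name members of the marker lists. Some of the genes the rule allows are not reported here. After the data were seen, list members that lost their call in a leave-out were mostly left unnamed. The rule allows 104, 17 and 65 called genes in the first 3 comparisons, of which 98, 6 and 46 stayed past the threshold whichever library was left out.

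Replicates were compared before averaging by a chi-square test of their counts. Each pair differed by more than sampling noise, with chi-square per degree of freedom from 1.14 to 9.02. No library was thus taken as another library sequenced again. The test cannot tell separate seed batches from separate preparations of a single batch. The tests were tried on simulated counts with 100 genes changed by a log2 fold change of 1 and 100 by 2 among 15301 genes. There edgeR recovered 78 and 93 for 7 d against 1 d and 72 and 93 for 14 d against 7 d. For darkness against 14 d of light it recovered 61 and 95, and false calls were 19, 7 and 5. Each gene was drawn independently, so the simulation held no shift shared by the genes of a library. Recovery may differ in the real data, where libraries of 7 d and 14 d light differ within a condition. Recovery and false calls may also differ for 7 d against 1 d, where 60.4% of tested genes were called, far more than were changed here. Alternatives fixed in advance were DESeq2 1.42.0 with its Wald test, DESeq2 size factors in edgeR, scaling by total counts, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, the replicate number as a block, only the compared groups in the fit (with the expression filter applied anew to their 6 libraries), and leaving out each library in turn. Regroupings of 6 libraries were fitted on the 15301 genes of the full model, so their counts for the real groups differ from those of that setting. Others were added after seeing the data: removal of the trends of each library on gene length and read density (spline offsets with 4 degrees of freedom each), the slope of log2 CPM on gene length of each library as a covariate, counts corrected for the limit of 1 read per base, only genes under 0.05 reads per base, and leaving out the 4 libraries with the steepest length trend (14 d light replicates 1 and 3, 7 d light replicate 3 and dark replicate 2). Leaving out those 4, which have the most negative slopes, keeps only replicate 2 of 14 d light. Counts of calls and list tests for comparisons with 14 d light in that setting are therefore not given. No genome was used here, so gene positions are not given.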

Results

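Transcript levels were measured by RNA-seq of polyadenylated RNA in imbibed seeds of *Aethionema arabicum*, a Brassicaceae relative of Arabidopsis, from the Cyprus accession. Seeds lay on wet paper at 14 °C under white light of 100 µmol m-2 s-1 for 1 d (23 h), 7 d or 14 d, or for 7 d followed by 7 d of darkness, and intact seeds that had not germinated were harvested. Each of the 4 conditions had 3 libraries, 12 in all. The series addresses secondary dormancy induced by light, that is, the loss of the ability to germinate in seeds held under light. The deposited table gives read counts for 24932 gene models, and 15301 of them had enough counts to be tested. Library totals were 3387609 to 3996148 counts after 1 d of light, 1596668 to 2689668 after 7 d and 916523 to 2448092 after 14 d. They were 1299536 to 1900418 after light and then darkness.

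The first principal component of log2 CPM held 65.2% of the variance and placed the 3 libraries of 1 d light at -104.3, -105.2 and -108.5, far from the other 9, which lay between 6.9 and 63.4. The second component held 11% and placed the dark-kept seeds at 25.3 to 44.3 and the 14 d light seeds at -49.0 to -5.6. The libraries of 7 d and 14 d light did not separate by condition. On the first and second components, replicate 3 of 7 d light (29.7 and -24.6) lay nearest to replicate 3 of 14 d light (37 and -36.9). Replicate 2 of 14 d light (15.2 and -5.6) lay nearest to replicates 1 (6.9 and 1.1) and 2 (7.8 and -1.1) of 7 d light.

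**Figure D1:**
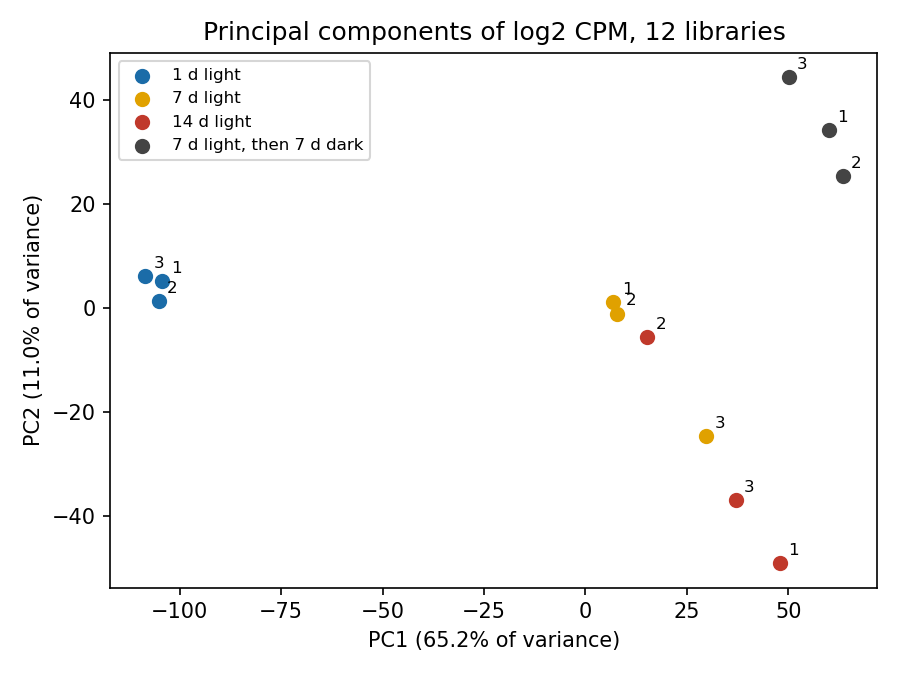
Scores of the 12 libraries on the first and second principal components of log2 CPM (axes in score units, with the percent of variance in the axis labels); each point is a library, numbered by replicate and coloured by condition. The 3 libraries of 1 d light stand apart at -104.3 to -108.5 on the first component, and the libraries of 7 d and 14 d light are interleaved.

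The comparison of 7 d with 1 d of light asks how seeds kept in light differ from seeds after their first day. Most tested genes of the wall loosening and cell cycle lists were lower after 7 d, and the tested seed storage and oil body genes were higher. The 13 tested genes of the wall loosening list comprised 9 that fell and 3 that rose (9 and 3 adjusted over the list alone), with a median log2 fold change of -0.98. Among those that fell were 3 genes of expansins, which loosen cell walls during growth: EXPA1 (Aa31LG4G11240) went from 76.5 ± 6.65 to 1.32 ± 0.81 CPM (SD, n = 3 each), EXPA9 (Aa31LG1G22490) from 67.2 ± 1.33 to 1.24 ± 1.14 CPM, and EXPA2 (Aa31LG11G6160) from 18.6 ± 1.77 CPM to no count at 7 d, at least 40.7-fold lower. Among genes of xyloglucan-modifying enzymes, XTH4 had a log2 fold change of -5.79 ± 0.32 (SE) and XTH16 (Aa31LG8G10270) of -1.28 ± 0.13. In the cell cycle list, 6 of 7 genes fell and 1 rose (6 and 1 adjusted over the list alone). The replication licensing genes MCM2, MCM5 and MCM7 had log2 fold changes of -2.58 ± 0.26, -3.01 ± 0.35 and -3.24 ± 0.33, while the mitotic kinase gene CDKB2;1 rose by 1.59 ± 0.13.

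The 8 called genes with the largest falls, among those paired with a described Arabidopsis gene and with a mean of at least 8 CPM, were the following. A subtilase (Aa31LG9G7400) had 59.6 ± 2.33 CPM after 1 d and no count after 7 d, at least 130-fold lower. Cysteine proteinase 1 (Aa31LG6G14100) was 523-fold lower (95% counting interval 93.7 to 20700), the extensin-like gene Aa31LG1G2640 260-fold lower (46.5 to 10300), and gamma-tocopherol methyltransferase (Aa31LG2G2160), an enzyme of vitamin E synthesis, 144-fold lower (39.7 to 1190). A gene model paired with the ribosomal protein gene RPL4A (Aa31sc350G40) was 232-fold lower (41.5 to 9200). How reads were divided among the models paired with this gene is not given in the sources used here, so its fold is uncertain. SKS16 (-6.40 ± 0.37) and the arabinogalactan protein gene AGP30 (-6.13 ± 0.34) were also in this set, with EXPA9. The 8 largest rises included a major facilitator superfamily transporter (Aa31LG3G2490, log2 fold change 5.96 ± 0.23) and a flavin-containing monooxygenase (Aa31LG10G5010, 66.9-fold higher, 95% counting interval 17.9 to 563). The others were a UPF0114 family gene (Aa31LG9G12720, 5.37 ± 0.35), PPC1 (Aa31LG1G15670, a phosphoenolpyruvate carboxylase, 4.39 ± 0.36), a thioredoxin family gene (Aa31LG9G16810, 4.2 ± 0.51), a U-box kinase (Aa31LG1G16490, 4.07 ± 0.31), RIP2 (Aa31LG4G2530, 4.06 ± 0.34) and the transcription factor gene MYB94 (Aa31LG4G16350, 3.99 ± 0.27). Adjusted p-values of these 16 genes ranged from 8.21e-09 to 1.49e-05.

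Abscisic acid (ABA) is the hormone that keeps seeds dormant, and gibberellin (GA) promotes germination. Of 7 tested ABA biosynthesis genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone). The cleavage enzyme gene NCED6 rose from 22.2 ± 0.87 to 90.8 ± 11.1 CPM (log2 fold change 2.03 ± 0.14, adjusted p = 2.25e-07), while NCED5 fell from 106 ± 6.78 to 40.3 ± 4.84 CPM (-1.40 ± 0.13). Of 3 ABA 8'-hydroxylase genes, which break down ABA, 2 fell and none rose (the same adjusted over the list alone): CYP707A2 (-0.92 ± 0.15) and a CYP707A3 copy (Aa31LG9G7680, -1.52 ± 0.22). ABA receptor and kinase genes split 1 up and 6 down of 11 (2 and 6 adjusted over the list alone). PYL8 (Aa31LG3G9320) was at least 22.2-fold lower, PYL6 was 60.6-fold lower (95% counting interval 10.6 to 2410) and PYL2 had a log2 fold change of -1.12 ± 0.14. Of 7 clade A PP2C genes, whose phosphatases restrain ABA signalling, 1 rose and 4 fell (1 and 4 adjusted over the list alone). HAB1 rose by 1.55 ± 0.14 and ABI2 fell by 2.08 ± 0.2. ABA-responsive transcription factor genes were 3 up and 2 down of 7 (3 and 2 adjusted over the list alone). Copies of ABF1 rose by 1.95 ± 0.1 (Aa31LG10G4330) and 2.32 ± 0.21 (Aa31LG8G6070), and ABI4 fell by 1.87 ± 0.12.

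In the GA biosynthesis list, 2 of 8 tested genes rose and 3 fell (2 and 3 adjusted over the list alone). GA3OX1 (Aa31LG7G270), which makes bioactive GA, fell from 14.7 ± 1.23 CPM to 1 count over 3 libraries, 96.6-fold lower (95% counting interval 17.1 to 3840). GA3OX2 (-0.95 ± 0.17) and GA20OX1 (-0.72 ± 0.14) also fell, while GA20OX2 rose by 0.97 ± 0.17. Of 3 GA deactivation genes 2 fell (2 adjusted over the list alone), GA2OX8 (-1.66 ± 0.31) and the GA2OX2 copy Aa31LG6G5630 (-1.48 ± 0.31). The GA perception list was 3 up and 3 down of 7 (3 and 3 adjusted over the list alone), with the receptor gene GID1A at 1 ± 0.12 and the F-box gene SLY1 at 1.68 ± 0.27. Of 8 dormancy regulators, 3 rose and 2 fell (3 and 2 adjusted over the list alone). DOG1, the delay of germination gene, rose from 23.1 ± 2.06 to 39.2 ± 6.02 CPM (0.74 ± 0.19, adjusted p = 0.00478) and RDO5 from 48.4 ± 1.72 to 91.3 ± 11.2 CPM (0.91 ± 0.14). DOGL3 fell by 0.87 ± 0.24, and SPT was 35.5-fold lower (95% counting interval 6.14 to 1420).

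All 9 tested seed storage and oil body genes rose (9 adjusted over the list alone), with a median log2 fold change of 1.11: a cruciferin gene (CRA1 copy Aa31LG2G21900) by 1.33 ± 0.25, the albumin gene SESA4 by 2.09 ± 0.27 and the oleosin gene OLEO4 by 1.13 ± 0.29. Of 11 late embryogenesis abundant (LEA) and desiccation genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), among them LEA14 at 1.41 ± 0.25 and PER1 at 0.95 ± 0.28, whose call was lost without replicate 3 of 7 d light (adjusted p = 0.0542). Between libraries of a single condition, 14 d light replicate 1 (916523 counts) against replicate 2 (2448092), the storage list shifted by 1.26, the LEA list by 1.12, the cell cycle list by -0.73 and the dormancy list by 0.58 on the log2 scale. The ribosomal protein list shifted by 0.64 and the antioxidant list by 0.59, while the wall loosening list shifted by 0 and the ABA biosynthesis list by -0.24. This pair differed the most of all replicate pairs (chi-square per degree of freedom 9.02), so its shifts do not stand for replicates in general. No count exceeded 1 read per base of gene length in gene models of 300 bp or longer (highest 0.996). The change from 1 d to 7 d differed by read density, from a median of -0.45 over 2037 genes under 0.01 reads per base to 0.61 over 257 genes above 0.3. With the trends of each library on gene length and read density removed, a step chosen after the data were seen, the medians were 0.59 for the storage list and 0.25 for the LEA list.

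**Figure D2:**
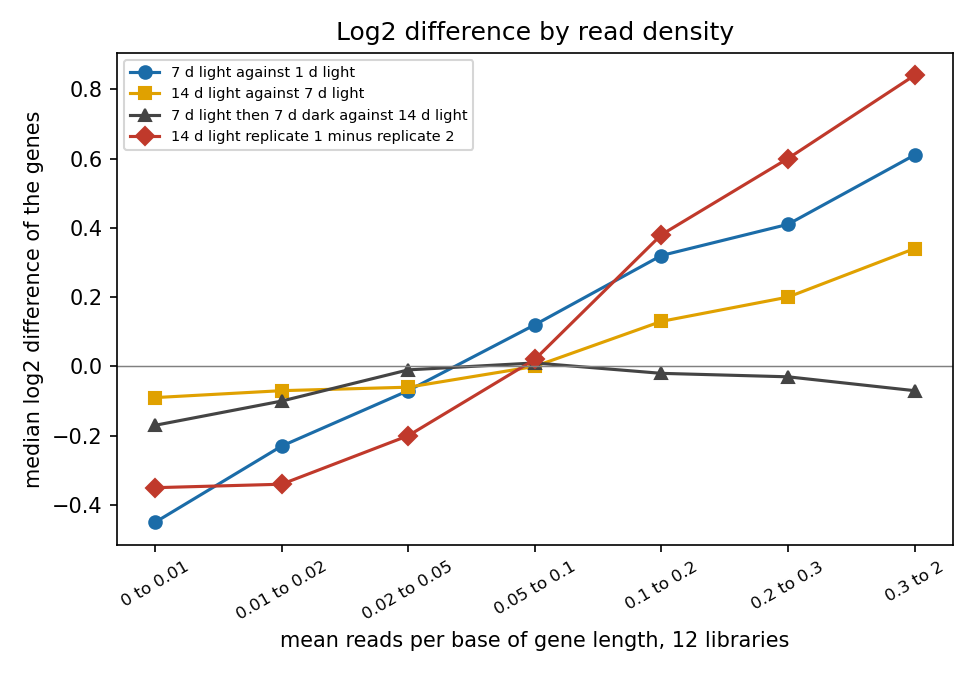
Median log2 difference of the tested genes (vertical axis) in classes of mean reads per base of gene length over the 12 libraries (horizontal axis), for 3 comparisons of conditions and for 14 d light replicate 1 minus replicate 2. The difference of 7 d from 1 d light runs from -0.45 to 0.61 and that between the replicates from -0.35 to 0.84, while that of darkness from 14 d light stays between -0.17 and 0.01.

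Light-related lists went both ways in the first week. Of 17 nuclear photosynthesis genes 8 rose and 6 fell (9 and 6 adjusted over the list alone), from LHCB6 (1.69 ± 0.14) and PSAN (1.51 ± 0.19) to PSBP1 (-1.04 ± 0.15) and LHCB1.4 (-0.98 ± 0.17). Light- and UV-induced photoprotection genes were 6 up and 4 down of 13 (6 and 4 adjusted over the list alone). The flavonoid enzyme genes FLS1 (Aa31LG3G17900) and F3H rose, by 1.3 ± 0.17 and 0.88 ± 0.21, and CHI (-0.76 ± 0.13) and RUP1 (-1.93 ± 0.3) fell. Photoreceptor and light signalling genes were 8 up and 5 down of 20 (8 and 5 adjusted over the list alone), with PIF5 at 2.67 ± 0.37. Clock genes were 8 up and 2 down of 17 (8 and 2 adjusted over the list alone), including RVE8 (1.5 ± 0.1), RVE1 (1.1 ± 0.13) and ELF3 (0.79 ± 0.1). Cytosolic ribosomal protein genes were 5 up and 7 down of 25 (4 and 7 adjusted over the list alone), with RPL4A (Aa31LG1G22050) at -0.89 ± 0.1. Smaller lists gave 1 up and 3 down of 7 heat shock genes (HSP101 0.9 ± 0.14, HSP22 -1.4 ± 0.21), 3 up and 1 down of 6 antioxidant genes (CAT1 0.85 ± 0.13) and 3 up and 1 down of 5 dark- and starvation-induced genes (ATG8E 1.42 ± 0.26). In the nitrate and ethylene list 1 of 5 rose (the nitrate transporter NRT2.7, 0.99 ± 0.1), and 1 of 3 embryo maturation regulators rose. Adjusted over the list alone, the counts of these 5 lists were the same.

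Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4695 genes higher and 4548 lower after 7 d than after 1 d, 60.4% of those tested. Of these, 1653 and 2199 changed at least 2-fold. The higher share of the calls, 50.8%, depends on the setting: it was 46.9 to 48.9% when each of the 12 libraries was left out, 48.3% with DESeq2, 41.6% under scaling by total counts alone and 51.9% with the length slope of each library as a covariate. Set tests with a preset correlation called wall loosening lower (adjusted p = 5.97e-06, but adjusted p = 0.183 with an estimated correlation) and cell cycle lower (0.00213, adjusted p = 0.581 with an estimated correlation). They called clock higher (0.0405, adjusted p = 0.183 with an estimated correlation) and storage higher (0.041, adjusted p = 0.826 with an estimated correlation). The storage call was lost without 1 d light replicate 3 (adjusted p = 0.0586), without 7 d light replicate 3 (0.106) and with the trends removed (0.0534), and the clock call without 1 d light replicate 2 (0.0527). With no filter on low counts the cell cycle and clock calls were lost (adjusted p = 0.0909 and 0.0504). Fry also called lists that camera did not (camera adjusted p 0.233 to 0.754). By fry, ABA biosynthesis (adjusted p = 0.00632), ABA-responsive factors (0.00185) and dark and starvation (0.00632) were higher. ABA receptors and kinases (0.000263), clade A PP2C (0.000403), GA biosynthesis (0.00682), GA perception (0.00312) and heat shock (0.00956) were lower. Each of these lists held called genes going both ways.

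The second week of light was examined by comparing 14 d with 7 d. A gene model paired with the plastid gene for the large subunit of Rubisco (Aa31sc227G10) rose from a mean of 10.1 to 93.5 CPM, a log2 fold change of 3.15 ± 0.21 (adjusted p = 2.04e-05). Other models paired with plastid genes rose as well: an ATP synthase subunit C gene (Aa31csc39G180) by 2.45 ± 0.36, and NADH dehydrogenase genes Aa31LG5G21720 and Aa31sc932G10 by 1.86 ± 0.28 and 1.86 ± 0.33. An auxin efflux carrier family gene (Aa31LG8G14790) rose by 1.22 ± 0.16, SESA4 by 1.41 ± 0.25, and a gene model paired with the mitochondrial ATMG00710 (Aa31LG10G9900) by 1.26 ± 0.22. Among the genes that fell were the cutin synthesis gene GPAT4 (Aa31LG1G10980, -2.16 ± 0.32), a PLAT/LH2 family gene (Aa31LG7G14560, -1.81 ± 0.19) and PSBP1 of photosystem II (-1.54 ± 0.2). Others were a DUF1645 gene (Aa31LG1G28780, -1.5 ± 0.22), ALDH11A3 (Aa31LG7G12540, -1.32 ± 0.21), SBT1.3 (Aa31LG3G8200, -1.28 ± 0.21) and a xanthine/uracil permease gene (Aa31LG11G750, -1.26 ± 0.23).

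Among hormone genes in the second week, CYP707A2 rose from 54.2 ± 7.52 to 107 ± 11 CPM (0.96 ± 0.16, adjusted p = 0.0179), the only one of 3 ABA catabolism genes called (1 higher and 1 lower adjusted over the list alone). No ABA biosynthesis gene (1 higher adjusted over the list alone) and no GA biosynthesis gene (1 lower adjusted over the list alone) was called over all genes. NCED5 had a log2 fold change of 0.6 ± 0.14 (adjusted p = 0.114), GA20OX1 of -0.9 ± 0.2 (0.0859) and the GA2OX2 copy Aa31LG6G5630 of 1.6 ± 0.35 (0.0859). The log2 fold change of RDO5 was 0.61 ± 0.14 (adjusted p = 0.102) and that of DOG1 0.3 ± 0.2 (0.521). Of the dormancy regulators none was called over all genes and 2 were higher adjusted over the list alone. The storage list had 1 gene higher of 9, SESA4 (2 adjusted over the list alone), beside the shift of 1.26 between 14 d light replicates 1 and 2. The photosynthesis list had 1 gene lower of 17, PSBP1 (1 adjusted over the list alone). In no other list was a gene called over all genes. Adjusted over the list alone, 3 heat shock genes, 1 ABA receptor or kinase gene and 1 ABA-responsive factor were higher. So were 1 wall loosening gene, 1 endosperm marker and 1 root marker. The root marker was the only tested member of its list, so its p-value is in effect unadjusted. Of the GA deactivation genes 1 was higher and 1 lower.

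In all, 25 genes were higher and 22 lower after 14 d than after 7 d, and 1814 of 15301 had an unadjusted p under 0.05. DESeq2 called 77. With only the 6 libraries of both conditions in the fit, 21 were higher and 3 lower, and 9 of these 24 were among the 47. The higher share, 53.2%, was 42.4% without 7 d replicate 3, 77.3% without 14 d replicate 3 and 72.1% without 1 d replicate 1. Set tests with a preset correlation called 5 lists higher: storage (adjusted p = 7.77e-06), LEA (0.0188), dormancy regulators (0.0295), photoprotection (0.0295) and ABA receptors and kinases (0.0444). All 5 lost the call, with adjusted p = 0.575 with an estimated correlation for 4 of them and 0.589 for LEA. With fry the adjusted p was 0.103 for receptors and kinases, 0.424 for LEA and 0.216 for the other 3. Leaving out the 4 libraries of steepest length trend keeps only replicate 2 of 14 d light, so no list test is given for that setting. The LEA call was also lost without 7 d replicate 1 (0.102), 7 d replicate 2 (0.0652), 14 d replicate 1 (0.371) or 14 d replicate 3 (0.0821). Photoprotection lost its call without 7 d replicate 1 (0.12), 7 d replicate 2 (0.0652) or 14 d replicate 3 (0.0991), and with only the 6 libraries in the fit (0.1). Dormancy regulators lost theirs without 7 d replicate 2 (0.111), 14 d replicate 1 (0.0585) or 14 d replicate 3 (0.107). The receptor and kinase list lost its call without 1 d replicate 1 (0.0647) or 2 (0.0558), without 7 d replicate 1 (0.102), 2 (0.0652) or 3 (0.0836), and without 14 d replicate 2 (0.0802) or 3 (0.107). It lost it also with no filter on low counts (0.244), with a filter of 1 CPM (0.196) and with DESeq2 size factors (0.0544).

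The libraries of 7 d and 14 d light differed within a condition. In counts compared gene by gene, chi-square per degree of freedom was 1.32 for 7 d replicates 1 and 2 and 1.45 for 14 d replicates 1 and 3, but 6.04 and 6.41 for 7 d replicate 3 against the other 7 d libraries. It was 7.02 and 9.02 for 14 d replicate 2 against the other 14 d libraries. Across conditions it was 1.45 for 7 d replicate 3 with 14 d replicate 3 and 1.9 for 7 d replicate 1 with 14 d replicate 2, and 7.82 to 10.3 for 7 d replicates 1 and 2 with 14 d replicates 1 and 3. Without 14 d replicate 2 the count of calls was 1662, without 7 d replicate 3 it was 99, and without 7 d replicates 1 or 2 or 14 d replicates 1 or 3 it was 20, 13, 31 and 22.

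Of the 15 genes called and named for the second week, 4 kept their call whichever library was left out: the Rubisco large subunit model, the auxin efflux carrier gene, the PLAT/LH2 gene and PSBP1. The subunit C model lost its call without 7 d replicate 2 (adjusted p = 0.0755), Aa31LG5G21720 likewise (0.098) and GPAT4 without 14 d replicate 3 (0.0698). The DUF1645 gene lost it without 7 d replicate 2 (0.0603) or 14 d replicate 3 (0.0698), and CYP707A2 without 7 d replicate 2 (0.13), 14 d replicate 1 (0.0783) or 14 d replicate 3 (0.0762). ALDH11A3 and SBT1.3 lost theirs without 7 d replicates 1 or 2 or 14 d replicates 1 or 3, with adjusted p up to 0.107 and 0.102. SESA4, Aa31sc932G10, Aa31LG10G9900 and the permease gene lost theirs without 7 d replicates 1 or 2, 14 d replicate 1, 1 d replicate 3 or dark replicate 1, with adjusted p up to 0.182, 0.123, 0.147 and 0.184. All of these but Aa31LG10G9900 lost it also without 14 d replicate 3, SESA4 and the permease gene without dark replicate 2, and the permease gene without 1 d replicates 1 or 2 or dark replicate 3. With only the 6 libraries of both conditions in the fit, 2 of the 15 stayed past the threshold, the Rubisco large subunit model and the PLAT/LH2 gene.

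The comparison of 7 d of light and then 7 d of darkness with 14 d of light sets darkness against light in seeds of equal age. Among the 8 largest falls in the dark-kept seeds were 3 genes of flavonoid synthesis. Dihydroflavonol 4-reductase (DFR, Aa31LG9G12870) was at 3.73 ± 0.42 against 110 ± 26.4 CPM (log2 fold change -4.81 ± 0.27, adjusted p = 3.1e-07). A flavonoid 3-O-glucosyltransferase (UF3GT, Aa31LG3G9960) was at 7.11 ± 1.93 against 188 ± 39.8 CPM (-4.66 ± 0.22), and FLS1 (Aa31LG3G17900) at 3.9 ± 1.6 against 78.7 ± 12.3 CPM (-4.34 ± 0.27). Of 13 photoprotection genes 10 fell and none rose (13 lower adjusted over the list alone), with a median of -2.5, and 3 were not called over all genes. They included the early light-induced gene ELIP1 (-3.82 ± 0.22), CHI (-2.5 ± 0.18) and the bZIP factor gene HYH (-2.24 ± 0.25). OHP1 was 9.76-fold lower (95% counting interval 3.04 to 50) and RUP1 27.3-fold lower (4.52 to 1120). Other large falls were SPA3 (Aa31LG10G2040, at least 25.4-fold), a UDP-glycosyltransferase (Aa31LG9G1940, -6.18 ± 0.47), a major facilitator superfamily gene (Aa31LG9G9720, 48.8-fold lower, 95% counting interval 8.37 to 1970) and the acyl carrier protein gene ACP4 (37.1-fold lower, 6.27 to 1500).

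The extensin-like gene and EXPA1 were among the 8 largest rises in darkness. The extensin-like gene Aa31LG1G2640, with no count after 14 d of light, reached 6.29 ± 1.29 CPM in dark-kept seeds, at least 9.9-fold higher, and EXPA1 reached 3.98 ± 1.9 CPM, 19.5-fold higher (95% counting interval 3.09 to 809). Their levels after 1 d of light had been 39.9 ± 3.73 and 76.5 ± 6.65 CPM. The EXPA1 call was lost without 14 d light replicate 2 (adjusted p = 0.0511) or without replicate 3 of the dark-kept seeds (0.0514). A pectin methylesterase inhibitor family gene (Aa31LG2G310) rose by 3.38 ± 0.28, a lipid transfer family gene (Aa31LG8G12220) by 3.26 ± 0.42 and Aa31LG6G9310 of the adenine nucleotide alpha hydrolase family by 2.97 ± 0.25. A kinase-interacting family gene (Aa31LG2G10930) rose by 2.39 ± 0.38, XTH11 (Aa31LG4G17200) by 2.21 ± 0.21 and the stomatal patterning gene EPF1 (Aa31LG8G17790) by 2.2 ± 0.21. In the wall loosening list as a whole, 1 of 13 genes rose and 1 fell (1 and 2 adjusted over the list alone), the fall being MAN5 (Aa31LG2G22180, -1.06 ± 0.19).

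**Figure D3:**
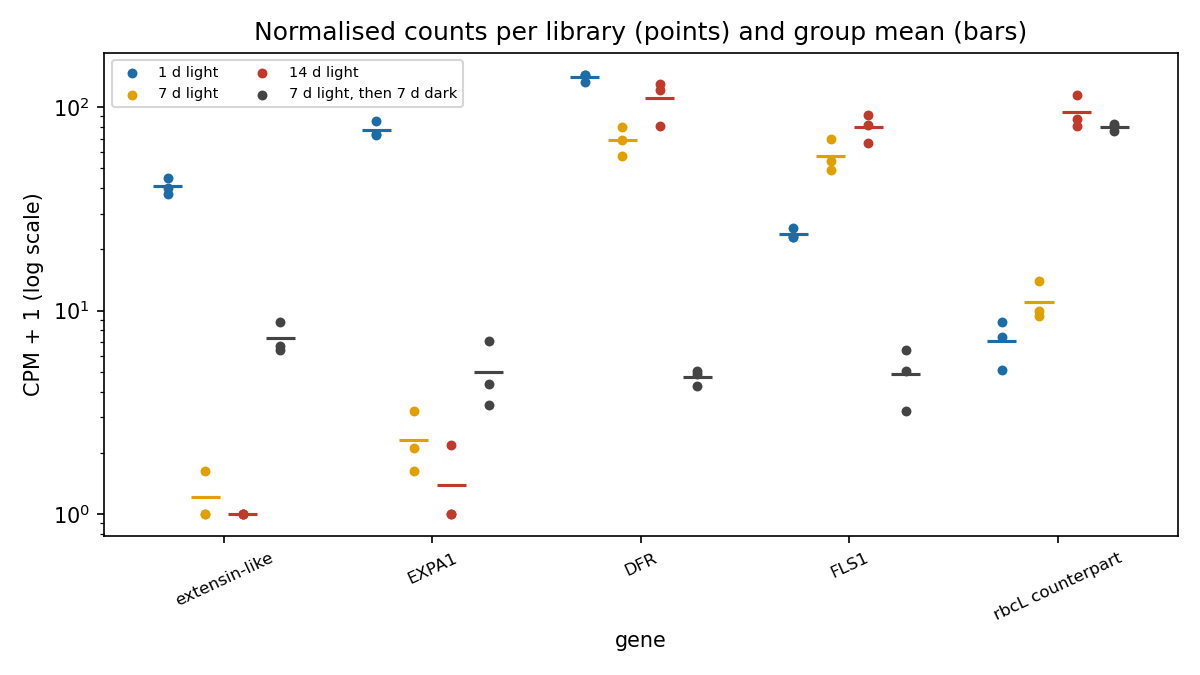
Normalised counts (CPM + 1, log scale) of 5 genes (horizontal axis) in each of the 12 libraries (points), with the mean of each condition (bars). The extensin-like gene and EXPA1 are high after 1 d of light and low later, DFR and FLS1 are low in dark-kept seeds, and the model paired with the plastid Rubisco large subunit (rbcL) is higher in all 6 libraries taken after 14 d (75 to 114 CPM) than in the 6 taken after 1 d and 7 d (4.1 to 12.9 CPM).

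Hormone genes changed in darkness as follows. CYP707A2 fell from 107 ± 11 to 26.8 ± 8.27 CPM (-2.01 ± 0.18, adjusted p = 1.35e-05), the only one of 3 ABA breakdown genes called (2 lower adjusted over the list alone). ABA biosynthesis genes were 2 up and 2 down of 7 (2 and 3 adjusted over the list alone). NCED5 fell by 1.73 ± 0.16, and NCED6 rose by 0.63 ± 0.14, a call lost without 14 d light replicate 3 (adjusted p = 0.0511) and with only these 6 libraries in the fit (0.0576). GA biosynthesis genes were 2 up and 1 down of 8 (2 and 1 adjusted over the list alone). GA20OX2 rose from 35 ± 2.22 to 107 ± 11.7 CPM (1.61 ± 0.17), GA20OX1 rose by 1.01 ± 0.2, and GA3OX2 fell from 24.4 ± 1.72 CPM by 3.58 ± 0.35 on the log2 scale. Copies of the GA-inactivating gene GA2OX2 went opposite ways. Aa31LG10G6850 fell from 21.8 ± 6.5 to 0.91 ± 0.41 CPM (-4.51 ± 0.53) and Aa31LG6G5630 rose from 23.9 ± 3.04 to 89.6 ± 21.4 CPM (1.89 ± 0.26). The list of 3 GA deactivation genes had 1 up and 1 down (1 and 2 adjusted over the list alone). Of 8 dormancy regulators 2 rose (2 adjusted over the list alone), DOGL3 among them by 1.21 ± 0.24, while DOG1 had a log2 fold change of 0.43 ± 0.2 (adjusted p = 0.181). ABF1 (Aa31LG10G4330) rose by 0.67 ± 0.1, and of 7 ABA-responsive factors 1 rose and 1 fell (1 and 1 adjusted over the list alone). ABA receptors and kinases were 3 up and 1 down of 11 (3 and 2 adjusted over the list alone), clade A PP2C genes 1 up and 1 down of 7 (1 and 3 adjusted over the list alone) and GA perception genes 2 up and 1 down of 7 (3 and 1 adjusted over the list alone). The GA perception list shifted by -0.66 between 14 d light replicates 1 and 2.

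Clock genes were 5 up and 6 down of 17 in darkness (5 and 7 adjusted over the list alone). LHY rose by 1.34 ± 0.17 and RVE1 by 0.68 ± 0.14, and PRR9 (-2.37 ± 0.22) and ZTL (-1.93 ± 0.15) fell. PIF5, which encodes a factor degraded in light, rose by 1.78 ± 0.25, within a list of 5 up and 2 down of 20 (5 and 3 adjusted over the list alone). In the nitrate and ethylene list 3 of 5 fell (3 adjusted over the list alone), including nitrate reductase NIA2 (-1.51 ± 0.22) and NRT2.7 (-0.73 ± 0.11). The median of this list was -0.77, beside a shift of -0.63 between 14 d light replicates 1 and 2, the replicate pair that differed most. Nuclear photosynthesis genes were 2 up and 3 down of 17 (3 and 4 adjusted over the list alone), PRK (-2.7 ± 0.33) among the latter. Antioxidant genes were 2 down of 6 (1 up and 3 down adjusted over the list alone), with FSD1 at -0.74 ± 0.15. Ribosomal protein genes were 2 down of 25 (2 adjusted over the list alone), with RPL4A (Aa31LG1G22050) at -0.6 ± 0.1. In the cell cycle list 1 of 7 fell (2 adjusted over the list alone), in the heat shock list 1 of 7 fell (1 adjusted over the list alone) and in the dark and starvation list 1 of 5 rose (1 adjusted over the list alone). No embryo maturation regulator of 3 was called. Storage and LEA lists had none called of 9 and 11, over all genes or over the list alone, with medians of -0.15 and -0.08.

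Darkness against 14 d of light gave 925 genes higher and 1074 lower, of which 179 and 508 changed at least 2-fold. The higher share of the calls, 46.3%, was 39% under scaling by total counts alone and 50.7% without 14 d light replicate 2. In settings chosen after the data were seen it was 56% with length and density trends removed and 51.6% with the slope covariate. Set tests with a preset correlation called photoprotection lower (adjusted p = 1.09e-34, and adjusted p = 0.0018 with an estimated correlation) and nitrate and ethylene lower (0.00213, adjusted p = 0.331 with an estimated correlation, 0.149 with no filter on low counts). They called clock lower (0.0454, adjusted p = 0.194 with an estimated correlation, 0.24 with no filter on low counts). The clock call was lost also without 7 d light replicate 3 (0.0526) and 14 d light replicates 1 (0.0641) or 2 (0.0599). The same held without replicate 1 (0.0503), 2 (0.0927) or 3 (0.0687) of the dark-kept seeds. The count of calls was 1259 without 14 d light replicate 3, 1216 and 1189 without replicates 1 and 3 of the dark-kept seeds and 856 with only these 6 libraries in the fit. It was 5245 with the length slope of each library as a covariate. No count is given without the 4 libraries of steepest length trend, where 14 d light keeps only replicate 2.

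Across the whole light series, 14 d against 1 d, 4867 genes were higher and 4836 lower. The higher share, 50.2%, was 46.9 to 49.2% when each of the 12 libraries was left out, 40.2% under scaling by total counts alone and 52.7% with the slope covariate. NCED6 (1.72 ± 0.15), DOG1 (1.05 ± 0.2) and RDO5 (1.52 ± 0.14) were higher at 14 d, NCED5 (-0.80 ± 0.13) was lower, and CYP707A2, at 0.04 ± 0.15, was not called. Dark-kept seeds against 7 d light seeds gave 1289 higher and 1529 lower. The higher share of these calls, 45.7%, was 34.6% under scaling by total counts alone, 50.3% without 14 d light replicate 2, 56.3% with trends removed, 52.4% with the slope covariate and 52.2% without the 4 steepest libraries. The count of calls, 2818, was 1705 and 1645 without 7 d replicates 1 and 2, and 1609 and 1686 without dark replicates 1 and 2. In that comparison GA20OX2 rose by 1.29 ± 0.16 and RDO5 by 1.15 ± 0.13, DFR (Aa31LG9G12870) fell by 4.14 ± 0.28, and EXPA1, at 1.58 ± 0.55 (adjusted p = 0.0635), was not called.

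Against 1 d of light, dark-kept seeds had 5075 genes higher and 5430 lower, 48.3% higher, and 38.6% under scaling by total counts alone but 52.3% with trends removed. The balance of rises and falls is thus not settled in these comparisons. EXPA1 stayed below its 1 d level by a log2 fold change of -4.17 ± 0.26, EXPA9 by -4.76 ± 0.26, MCM2 by -2.89 ± 0.3, GA3OX2 by -4.22 ± 0.3 and CYP707A2 by -1.97 ± 0.17. DOG1 was above it by 1.48 ± 0.19, RDO5 by 2.06 ± 0.14, NCED6 by 2.35 ± 0.14 and SESA4 by 3.58 ± 0.27.

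Whether darkness moved genes back was tested on contrasts with no library in common, 7 d against 1 d of light and darkness against 14 d of light. Of 1427 genes called in both, 364 (25.5%) went opposite ways and 1063 the same way. Genes that rose in the first week and fell in darkness numbered 226, where independent lists would share 330, and those that fell and then rose numbered 138, against 275. Genes that rose in both numbered 527 (284 if independent) and genes that fell in both 536 (319). Among the reversals were the extensin-like gene Aa31LG1G2640, EXPA1, the UDP-glycosyltransferase Aa31LG9G1940 and FLS1. The count of opposite genes was 240 without 14 d light replicate 3, 210 without replicate 3 of the dark-kept seeds, 457 without 14 d light replicate 2 and 188 with 2-group fits. In settings chosen after the data were seen it was 1043 with the slope covariate and 202 for genes of low read density. Calls in the first-week and darkness contrasts changed as well: 11528 and 5245, and 5637 and 1035 in these settings. The count for independent lists was computed for the main fit only, so these counts do not show more or less reversal.

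Markers of other seed tissues were followed in all conditions. The endosperm-expressed gene ALE1 rose from 86.3 ± 2.79 CPM at 1 d to 178 ± 12 at 7 d. It was lower in darkness than after 14 d of light (-0.55 ± 0.12), a call lost with only those 6 libraries in the fit (adjusted p = 0.0509). ICE1 stood at 91.9 ± 6.06, 90.4 ± 7.05, 90.7 ± 4.1 and 79.5 ± 7.27 CPM after 1 d, 7 d and 14 d of light and in darkness. Of the 3 tested endosperm markers, 1 rose and 1 fell in the first week, none was called in the second and 1 fell in darkness (adjusted over the list alone, 1 and 1 in the first week, 1 higher in the second and 1 lower in darkness). Of the seed coat markers, TT12 had no count in any library, and MUM4 fell from 29.7 ± 0.49 to 6.76 ± 1.34 CPM in the first week, when both tested members fell (2 adjusted over the list alone). Neither was called later (1 lower in darkness adjusted over the list alone), and the list shifted by -0.95 between 14 d light replicates 1 and 2. The root hair gene RHD6, the only tested member of its list, fell from 21.9 ± 3.52 to 7.15 ± 1.45 CPM (-1.61 ± 0.23) in the first week and was not called later. With no other tested member, adjustment over the list alone leaves its p-value as it was. That unadjusted p-value was past the threshold in all 3 comparisons, the gene being higher in the second week and lower in darkness.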

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

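The removal of length and density trends, the slope covariate, the corrected counts, the low-density genes and the omission of the 4 steepest libraries were chosen after the results were seen. Counts of genes for 7 d and 14 d against 1 d of light and for darkness against 1 d moved by over 1.5 times in no setting but the low-density genes (5637, 5593 and 6240), where fewer genes are tested. Leaving out each library gave 7970 to 10042 for 7 d against 1 d. For 14 d against 7 d, in place of 47, the count was 25 with the replicate block, 85 with trends removed, 522 with the slope covariate, 96 without the 4 libraries, 77 with DESeq2, 24 with only these groups (21 higher and 3 lower, 9 of them among the 47), and 13 to 1662 when each library was left out (13 without 7 d replicate 2, 1662 without 14 d replicate 2, with 46 of the 47 among them). For darkness against 14 d light, in place of 1999, it was 5245 with the slope covariate, 1035 for low-density genes, 3763 without the 4 libraries, 856 with only these groups and 1189 to 2241 in the leave-outs. For darkness against 7 d light, in place of 2818, it was 5587, 1454 and 5419 in the first 3 of these settings and 1609 to 3800 in the leave-outs (1705 and 1645 without 7 d replicates 1 and 2, 1609 and 1686 without dark replicates 1 and 2). The count of opposite changes, 364, became 1043 with the slope covariate, 202 for low-density genes, 677 without the 4 libraries, 188 with 2-group fits and 210 to 457 in the leave-outs. Calls in both contrasts changed in these settings too, so these counts do not show more or less reversal. Of 12 list calls, 1 was kept with an estimated correlation. Fry called 17 lists. For 7 d against 1 d, those that camera did not call are given in Results. In darkness against 14 d light they were GA perception (fry adjusted p = 0.00683) and dark and starvation (0.0211), both higher. Of the 12, fry kept 7, and lost the 5 of 14 d against 7 d (adjusted p 0.103 to 0.424). With the slope covariate 4 of those 5 were lost (0.272 to 0.721). The clock call in darkness was lost with that covariate as well. With trends removed the receptor (0.212), LEA (0.141) and photoprotection (0.122) calls of 14 d against 7 d were lost. The LEA list for 14 d against 7 d turned lower with the slope covariate (adjusted p = 0.721) and without the 4 libraries (0.696), and DOG1 there went from 0.30 to -0.03 without the 4 libraries. The cause was not tested for these except as weighed under the other observations.

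Replicate numbers are shared by the conditions in the labels but do not pair the libraries: correlations of same-numbered deviations ran from -0.42 to 0.44, 4 of 18 were over 0.1, and 3 of 12 libraries correlated best with their own number. The replicate block left 25 calls for 14 d against 7 d, kept 9 of 15 named genes called there, ended the calls of the ABA receptor and kinase list there (adjusted p = 0.0641) and of the clock list in darkness (0.258), and moved no other count of genes by over 1.5 times. Scaling by total counts moved the median log2 fold change of all genes to -0.11, -0.16 and -0.24 for 7 d, 14 d and darkness against 1 d, and kept each call of the named genes. The 74 genes named in Results for 7 d against 1 d kept their direction in each setting that tested them. So did the 42 called genes named there for darkness against 14 d light. Among low-density genes 41 and 22 were tested, and 36 of the 42 with only these 2 groups. Of the first, 1 lost its call in a leave-out. Of the second, EXPA1, NCED6 and ALE1 lost theirs in the settings given with them. List members that lost a call in a leave-out were mostly left unnamed, so these genes do not stand for all calls. Of the called genes the rule allows, 98 of 104 and 46 of 65 kept their call in each leave-out. In simulated data for darkness against 14 d light, drawn without shifts shared by the genes of a library, 61 of 100 genes changed 2-fold were recovered. Of 100 changed 4-fold, 95 were recovered.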

Other observations

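The tests below on storage genes, on the count for 7 d against 14 d and on genes limited to 1 d were chosen after the results were seen; only the counts over other splits of the samples were fixed before. Gene models paired with Arabidopsis plastid genes, were picked as a group because some of them rose between 7 d and 14 d of light, so no test of the group is given. Of 14 tested, 7 were called higher there and none lower, with a median log2 fold change of 1.21, and 2 had negative values (-0.47 and -0.42, not called). Dark-kept seeds had 8 of 14 higher than 7 d light seeds and none lower, and none called against 14 d light, with a median of -0.10. Their share of all counts was 0.031 to 0.042% after 1 d of light, 0.038 to 0.055% after 7 d, 0.082 to 0.124% after 14 d and 0.085 to 0.106% in darkness. RNA was selected for poly(A) tails, so these counts cover only transcripts carried through that step. Some of the models, such as Aa31LG3G17860 and Aa31LG5G21720, have identifiers of the form that models paired with nuclear genes have. Whether their reads came from plastid or nuclear copies was not tested. Of 33 models paired with mitochondrial genes, 1 was called higher at 14 d than at 7 d (median 1.90). In darkness against 7 d, 18 were higher (median 1.95), and at 14 d against 1 d 17 were higher. None was lower in these, and none was called in darkness against 14 d. Plastid- and mitochondrion-paired models together held 0.208% of counts in 1 d light replicate 1, but 0.0619% and 0.0805% in replicates 2 and 3. That share was 0.0884 to 0.136% after 7 d, 0.230 to 0.375% after 14 d and 0.270 to 0.316% in darkness.

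A scan of 147 gene families by their description was made after seeing the data. Pentatricopeptide repeat (PPR) genes, which process organelle RNA, had 8 higher and 108 lower of 161 after 7 d against 1 d of light. Their median was -0.90 (camera adjusted p = 2.71e-07, adjusted p = 0.748 with an estimated correlation). Read density of these genes was not examined, and all genes under 0.01 reads per base had a median of -0.45 in this comparison. Other families, called in both directions, are not reported here. Flavonoid genes, of which no list was tested, went different ways, and those given here were named after their values were seen. Leucoanthocyanidin dioxygenase (3.51 ± 0.28, then -3.34 ± 0.31) and the regulator MYB12 (1.78 ± 0.24, then -1.78 ± 0.30) rose in the first week and were lower in darkness. DFR (Aa31LG9G12870, -1.04 ± 0.16, then -4.81 ± 0.27) and CHI (-0.76 ± 0.13, then -2.50 ± 0.18) fell in both, and F3H, which rose in the first week, was not called in darkness (-0.65 ± 0.21, adjusted p = 0.0611). The DNA repair gene photolyase 1 rose and then fell (1.77 ± 0.15, then -2.37 ± 0.19).

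Storage and oil body transcripts were higher after 7 d than after 1 d of light by a median of 1.11 over 9 genes. Without the 4 libraries of steepest length trend the median was 0.86, with 9 of 9 genes called. Of those 4 only 7 d light replicate 3 is in this comparison, so that library does not account for the whole rise. A length trend in the other libraries was not tested by this step. Leaving out 7 d light replicate 3 alone ended the list call (camera adjusted p = 0.106). The 9 genes had an estimated correlation of 0.93, so they are not 9 separate measurements. Correcting counts for the limit of about 1 read per base did not lower the median (1.18), under a model of that limit itself not tested. With all trends on length and density removed, a step not specific to the limit, the median was 0.59 (SD 0.40 over the 9 genes), 9 of 9 were called and the list test went from adjusted p = 0.041 to 0.0534. Removing trends can also take out real change, so what share of the rise follows such trends cannot be told apart, and a true rise in light stays open, as untested.

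Few genes were called between 7 d and 14 d of light. Of the 10 splits of these 6 libraries, the real one called 27 genes. The split that exchanges 7 d replicate 3 with 14 d replicate 2 called 5533. This points to a structure of the libraries other than their labelled condition. Plastid-paired genes kept to the labels (median log2 CPM in 14 d replicate 2 was 0.92 above the highest library labelled 7 d, and in 7 d replicate 3 was 0.77 below the lowest labelled 14 d), but they were picked because they rose under those labels. On the first principal component of all genes 14 d replicate 2 (15.2) lay below 7 d replicate 3 (29.7), as an exchange would give, so an exchange of those 2 libraries stays open. A trend on gene length that differs between libraries of a condition could account for part. With the slope of each library as a covariate 522 genes were called. This cannot separate length from any other difference between these libraries, since the slopes divide them the same way. They were 0.0744 and 0.0792 in 7 d replicates 1 and 2 and 0.0478 in 14 d replicate 2. In 7 d replicate 3 and 14 d replicates 1 and 3 they were -0.0808, -0.138 and -0.123. With trends removed the exchanged split still called 4003 and the real one 33. Differences in seed state or in preparation between libraries stay open, as the labels give no batch.

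After 1 d of light, 48 genes had at least 30 counts in each library and at most 6 over the other 9 libraries together, among them GA3OX1, EXPA2, PYL6 and PYL8. With a lower bound of 10 counts in each of the other 9 libraries, and at most 6 over the 3 of 1 d, 3 genes were found the other way. At the 1 d level a median of 217 counts, and 123 at the lowest, would be expected in the other 9 libraries. The minimum of 30 counts in each 1 d library made high values certain, so they are no independent test of depth. They show only that depth alone would not bring these counts to 6 or fewer. A different seed lot at 1 d, with blocks of genes that the other lot lacks, may leave neighbouring genes in the set: 3 pairs had adjacent identifier numbers, as many as in 0 of 10000 random lists matched on level (95th percentile 1), but only 6 of the 48 genes (12.5%) were in such pairs. That explanation and genes shut off during the first week of light cannot be told apart here, since 1 d seeds are a single condition.

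Splits of 6 libraries into 3 and 3 number 10, the real one included, too few for a share under 0.05. In 5 comparisons 1 of 10 splits, the real one, called as many genes. The real and highest other counts were 9693 and 0 for 7 d against 1 d of light, 926 and 122 for darkness against 14 d light, 9467 and 0 for 14 d against 1 d, 2116 and 0 for darkness against 7 d light, and 11644 and 0 for darkness against 1 d. For 14 d against 7 d of light, 2 of 10 splits, the real one included, called as many, with 27 and 5533. For opposite changes, 1 of 100 pairs of splits drawn, the real one with 196 genes, was as large, and the highest other was 9. This decides nothing, since no other split of the 7 d and 1 d libraries called a gene, so pairs with those could hold no opposite changes. The real groups with 1 contrast mirrored, not among the 100 drawn and looked at afterwards, gave 467.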
